A study of Homo sapiens with 4 samples.

How the data were processed

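Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in KHYG1, a human natural killer (NK) cell leukemia line grown with interleukin 2. The 4 libraries were 2 of cells given the solvent DMSO and 2 of cells given BAY 299, each harvested after 96 hours. Groups and replicate numbers came from the sample labels. Nothing in the labels says whether replicates were separate cultures, so every p-value across libraries measures only the spread between these libraries, which may be technical.

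The deposited data were 1 peak list per library in the narrowPeak layout. Reads were aligned with BWA 0.7.15 to GRCh38 (hg38) and peaks were called with MACS2 2.2.7.1, per the submitters' processing notes. Peaks were called on each library alone, as the peak names and their unbroken numbering in the deposited lists show. A control library, duplicate handling, and read shifting or extension are not given in the sources used here, and without a shift a cut site lies a few bases from its true position, far less than the width of a peak. The deposited score of a peak was 10 times its −log10 q, rounded down. The deposited fold enrichment of a peak was the ratio of the summit pileup plus 1 to the local background plus 1. The deposited −log10 p and −log10 q were MACS2's Poisson values for the summit, and the lowest −log10 q in the lists corresponds to a q threshold of 0.01. These values belong to the authors, describe 1 peak within 1 library, and were used to rank or filter peaks within a list. Their formula was also solved for the summit pileup and background of each peak, as described below.

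Peaks on autosomes and X entered the comparisons, and several summits in 1 interval counted once. No filter for artefact-prone sequence was applied here. Peaks of the 4 lists that shared at least 1 bp were merged into union regions. A region called in both DMSO libraries and neither BAY 299 library is termed DMSO-only, and the opposite pattern BAY 299-only. The 3 ways to divide 4 libraries into pairs were set side by side, since the pairs that mix treatments show how often libraries disagree without a treatment difference. Between 2 and 2 libraries the smallest two-sided exact permutation p is 0.333, so this test could not reach 0.05 for any value per library. Overlap was given as the Jaccard index of base pairs and as the share of peaks overlapping another list. Retention was computed in 10 equal bins of −log10 p within each list. Strength percentiles are ranks of −log10 p within 1 list, and lists of different lengths give different ranks to the same signal.

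Gene positions were those of NCBI RefSeq genes on GRCh38.p14, the build of the files, for 19974 protein-coding genes. The table used carries no strand, exons or alternative start sites, so a gene end is a window of 1 kb on each side of either end of the gene, in place of the transcription start site intended before the data were examined, and intronic or exonic positions were not assigned. A locus is the gene and 10 kb on each side. The 20 gene lists, fixed before the data were examined, held 430 genes, and all 430 were found in the table. Each list was tested for DMSO-only and for BAY 299-only genes or regions against those called in all 4 libraries with Fisher's exact test (two-sided) and Benjamini-Hochberg adjustment over the 20 lists. Genes and regions are not replicates, so these tests compare sets of regions and not the treatments. Genes were named by a rule fixed beforehand. It took the 12 genes per direction with the strongest gene-end region of that pattern, by the lower of the percentiles in the libraries with the call. It also took members of the lists with such a region (at most 6 per list), the 5 strongest regions per direction over 1 kb from a gene end, and BRD1, TAF1, PDCD1, CD274, IFNG, PRF1 and GZMB. Other genes named below are list members given as examples or were chosen after their values were seen. Motif analysis with 20 consensus sequences was planned and left out, because no genome sequence was used here. The result for 1 listed gene is not reported here.

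The depth of the libraries was not stated. Fold enrichment and −log10 p were solved together for the summit pileup, which came out whole within 0.01 for 100% of the peaks checked in each list. The lowest background was then taken as a measure of depth. The lists were thinned to equal depth, and to equal depth and equal pileup in shared regions, by binomial draws from these pileups (100 draws) followed by the same p threshold. For regions called in all 4 libraries, log2 pileups centred on the library median were tested with limma 3.58.1 (R 4.3.3), which estimates the spread from 2 libraries per group with help from all regions. On simulated data, all 2000 pileups counted as recovered, but any with a −log10 p below 2 were counted without being solved. The class of all 5394 regions was recovered, an easy case in which the edges of real peaks were moved slightly. The thinning, the limma test and a comparison matched on strength were added after the data were seen. Alternatives fixed beforehand were a −log10 q of at least 5, lists cut to the length of the shortest (12509 peaks), a reciprocal overlap of 50%, each library left out in turn, all sequences, a distance of 500 bp, other windows, other overlap measures and a replicate block. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.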

Results

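The data were ATAC-seq peak lists of the NK leukemia line KHYG1 after 96 hours with DMSO (n = 2) or BAY 299 (n = 2). BAY 299 is a chemical probe that binds the bromodomains of BRD1, a scaffold of histone acetyltransferase complexes, and of TAF1, the largest subunit of the general transcription factor TFIID. The comparison asked how accessible chromatin in NK cells differed when these bromodomains were blocked. The lists held 16180 and 16753 peaks in DMSO replicates 1 and 2, and 12509 and 15173 in BAY 299 replicates 1 and 2. They covered 8.11, 8.52, 6.0 and 7.63 Mb in the same order, with median widths of 436, 445, 423 and 440 bp. The background pileup, a measure of depth solved from the deposited values, was 0.701, 0.782, 0.609 and 0.693 fragments or reads per base. By this measure BAY 299 replicate 1 was the shallowest library, and it also had the lowest median pileup in shared regions (21, against 28, 31 and 27 in DMSO replicates 1 and 2 and BAY 299 replicate 2). Its list had the highest share of peaks at gene ends, 58.0%, against 48.8% to 51.6% in the others.

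Most strongly accessible regions were called with and without BAY 299. Of 20914 union regions, 10371 (49.6%) were called in all 4 libraries. Gene-end calls in all 4 libraries were found at 7846 of 19974 protein-coding genes, among them PRF1 and FASLG, which encode killing molecules of NK cells, IFNG, the gene of interferon gamma, and EOMES and TBX21, which encode transcription factors of the lineage. The 915 DMSO-only regions outnumbered the 103 BAY 299-only regions 8.88 to 1, and most regions of both kinds were weak calls away from gene ends. No gene list passed its test in either direction.

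The mean number of peaks was 16466.5 ± 405 (SD, n = 2) with DMSO and 13841 ± 1884 (SD, n = 2) with BAY 299, a difference of -2625.5 peaks or -15.9% (exact permutation test, p = 0.333, the smallest this test allows with 2 against 2). Without BAY 299 replicate 1 the difference was -1293.5 peaks. The DMSO-only regions were 6.83% of the 13399 regions called in both DMSO libraries, and the BAY 299-only regions were 0.938% of the 10984 called in both BAY 299 libraries. Regions called in 1 pair and not in the other numbered 1018 when the libraries were divided by treatment. They numbered 780 (159 and 621) when divided by replicate number and 653 (464 and 189) in the remaining division. The rarer pattern was in each case that of the pair with BAY 299 replicate 1. In addition, 1671 regions were missing in BAY 299 replicate 1 alone, against 442, 272 and 238 in BAY 299 replicate 2, DMSO replicate 1 and DMSO replicate 2. Leaving out single libraries moved these counts. The group that lost a library then needed 1 call, while the other group still needed 2. Regions called in 1 library alone counted for the group that lost a library. In the full lists these were 1706 and 2056 for DMSO replicates 1 and 2. They were 500 and 1207 for BAY 299 replicates 1 and 2. The ratio below thus sets unlike rules side by side and does not show how the excess depends on that library. Without BAY 299 replicate 1 there were 1360 DMSO-only and 1319 BAY 299-only regions, a ratio of 1.03, and without BAY 299 replicate 2 there were 2588 and 616. Without DMSO replicate 1 they were 3035 and 348, and without DMSO replicate 2 they were 2671 and 375. With all lists cut to the 12509 strongest peaks, the counts were 388 and 305, a ratio of 1.27.

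**Figure D1:**
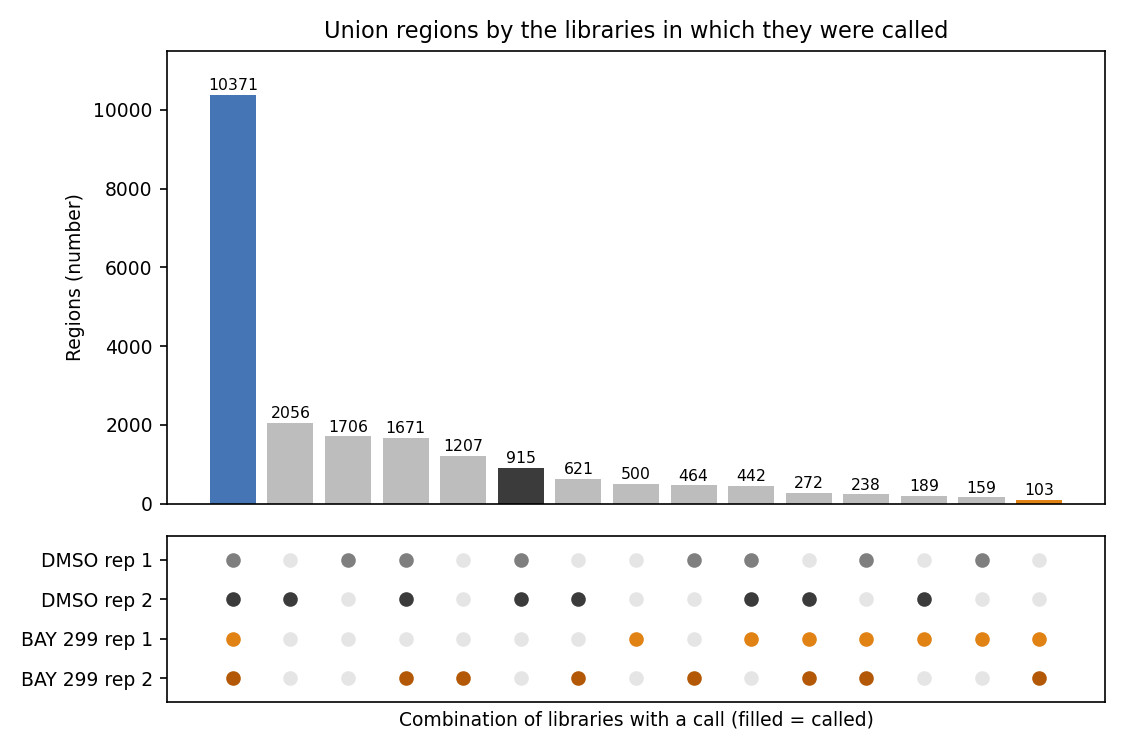
Bars give the number of union regions for each combination of libraries with a call, and filled dots under each bar mark the libraries that called it. The bar for all 4 libraries reaches 10371, the DMSO-only bar 915 and the BAY 299-only bar 103, while 1671 regions lacked a call in BAY 299 replicate 1 alone.

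Regions of each kind differed in strength and position. Regions called in all 4 libraries had a median percentile of 67.4 and 68.6 in the DMSO lists, and 63.5% of them lay at a gene end. DMSO-only regions had median percentiles of 21.3 and 22.8, and 23.1% lay at a gene end (95% exact binomial interval 20.4 to 25.9%, odds ratio 0.172 against regions in all 4 libraries, Fisher's exact p = 8.79e-126). BAY 299-only regions had median percentiles of 11.9 and 16.2 in the BAY 299 lists, and 34.0% lay at a gene end (24.9 to 44.0%, odds ratio 0.296, Fisher's exact p = 1.76e-09). Against regions of like strength, in a comparison added after the data were seen, the odds ratios were 0.273 (permutation p = 1e-05, the smallest the permutations can give) and 0.568 (permutation p = 0.01). Regions of mixed pattern lay at a gene end in 22.3% of cases. Among them, regions called only in 1 DMSO and 1 BAY 299 library did so in 21.9 to 29.6%, depending on the pair. A share below 63.5% is thus not particular to regions of 1 treatment.

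The strongest calls were retained almost completely between any of the libraries. In the strongest of the 10 bins of DMSO replicate 1, 99.9% of peaks overlapped a peak of DMSO replicate 2, 99.9% one of BAY 299 replicate 1 and 100% one of BAY 299 replicate 2. In its weakest bin, the shares were 38.3, 18.0 and 29.0%. The weakest bins of the BAY 299 lists did not follow treatment. In that of BAY 299 replicate 2, 21.3% overlapped BAY 299 replicate 1, against 39.7 and 43.7% for DMSO replicates 1 and 2. In that of BAY 299 replicate 1, 53.2% overlapped BAY 299 replicate 2, against 58.3 and 58.8% for DMSO replicates 1 and 2. The Jaccard index was 0.633 between the DMSO libraries and 0.589 between the BAY 299 libraries, and between treatments it ranged from 0.565 to 0.627. The mean within groups exceeded that between groups by 0.0108, with no test possible below p = 0.333 by exact permutation. At equal list length the excess was 0.0068.

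**Figure D2:**
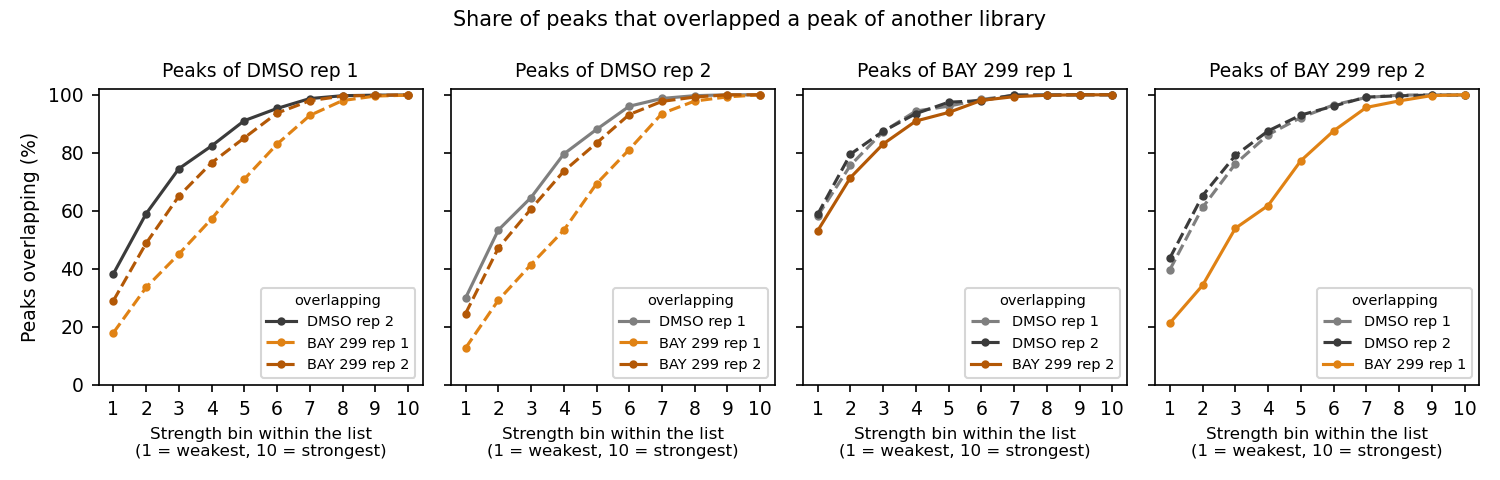
Each panel takes the peaks of 1 library in 10 bins of strength (x axis) and gives the percentage overlapping a peak of each other library (y axis), with solid lines for the same treatment and dashed lines for the other. The lines meet near 100% in the strongest bins and part in the weakest, where overlap with BAY 299 replicate 1 was lowest in the 3 other libraries.

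No gene of the cytotoxicity, cell cycle, AP-1, lineage transcription factor or ribosomal lists was DMSO-only or BAY 299-only at its gene ends. Among all protein-coding genes, 184 were DMSO-only and 26 BAY 299-only, against 7846 called in all 4 libraries. DMSO-only genes were 2.29% of the DMSO-only and shared genes together. With so few, their absence from lists this short is no sign that a list was spared. Among 18 cytotoxicity genes, 8 had a gene-end call in all 4 libraries, including PRF1, FASLG, TNFSF10 and NKG7, 7 had a mixed pattern and 3 had none. GZMB, the gene of the protease granzyme B, was called at its gene end in 3 libraries (chromosome 14, 24634109 to 24634533) and not in BAY 299 replicate 1. All 31 called genes of the 34 in the cell cycle list, such as MKI67, PCNA and CDK1, were called in every library, as were 32 of 34 ribosomal protein genes. Of 31 AP-1 and immediate early genes, 23 were called in all 4 libraries, among them JUN, FOS, FOSB and EGR1. Of 30 other bromodomain and chromatin regulators, 23 were called in all 4, including EP300 and SMARCA4, and of 23 lineage transcription factors 9 were, including RUNX3, EOMES and PRDM1. The counts called in all 4 libraries were 5 of 20 inhibitory receptors and checkpoints, 4 of 17 cytokines and chemokines, 10 of 32 interferon response genes and 2 of 20 antigen presentation genes (CD74 and NLRC5). Of the antigen presentation genes, 16 lie in an interval of chromosome 6 with 1 region in any library.

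The activating receptor list came closest to the threshold at gene ends. HCST and TYROBP, neighbouring genes for the signalling adaptors of NKG2D and other activating receptors, share 1 DMSO-only region (chromosome 19, 35903691 to 35903950), so the list counted 2 DMSO-only genes against 3 called in all 4 libraries (CD2, CD244 and CD247). Its Fisher's exact p was 0.00499 and its adjusted p 0.0998. This test counted the shared region as 2 genes. Over loci, where regions are counted, the list held 2 DMSO-only regions and 18 in all 4 libraries (odds ratio 1.26, Fisher's exact p = 0.675). Without DMSO replicate 1 this list, Chemotaxis and adhesion, and Interferon response passed at gene ends (smallest adjusted p = 0.00244). In that setting a call in DMSO replicate 2, the deepest library by background, is enough on the DMSO side. SLAMF6, SH2D1B, S1PR1, CCR1, IFIT2 and OAS1, for example, were called in DMSO replicate 2 only. They lacked a call in DMSO replicate 1 as well, so the DMSO libraries disagreed on them. STAT5B and STAT5A, which encode signal transducers of interleukin 2, also shared a DMSO-only region (chromosome 17, 42288309 to 42288582), beside 18 of 25 cytokine receptor and JAK-STAT genes called in all 4 libraries, such as JAK1 and IL2RG (adjusted p = 0.505). Single genes of this pattern were CXCR3, a chemokine receptor (chromosome X, 71618460 to 71618701), GBP1, an interferon-induced GTPase (chromosome 1, 89064725 to 89065689), and BID, a pro-apoptotic gene (chromosome 22, 17773789 to 17774167). All of these regions lay below the 30th percentile of both DMSO lists. At equal list length the region of CXCR3 was still DMSO-only, while those of HCST and TYROBP, of STAT5B and STAT5A, of GBP1 and of BID had no excess of DMSO calls. This cut removed the weakest peaks of every list but the shortest, that of BAY 299 replicate 1. Regions low in the DMSO lists thus lost their own DMSO calls, which says nothing about their BAY 299 calls. GBP1 and BID also lost the pattern at a −log10 q of at least 5. FLT3LG, CXCR4, EZH2, KAT2A and E2F1 had a DMSO-only region at a gene end as well as another region called in all 4 libraries, and none of these 5 DMSO-only regions kept the pattern at equal list length. In the other direction, a BAY 299-only region lay at KLRC1, which encodes an inhibitory NK receptor (chromosome 12, 10454629 to 10454978), and at MKI67, whose gene ends were otherwise called in all 4 libraries. The KLRC1 region ranked at percentiles 1.99 and 16.9 and lost the pattern at the stricter threshold and at equal length, and as a gene KLRC1 was also called in DMSO replicate 2. The MKI67 region lost it at the stricter threshold. Over loci, Chemotaxis and adhesion held 7 DMSO-only regions, with examples at CXCR3, ITGAE, CXCR4 and ITGAL, against 20 in all 4 libraries (odds ratio 3.99, adjusted p = 0.0945). Without DMSO replicate 2, where a call in DMSO replicate 1 is enough on the DMSO side, the NK and lymphoid transcription factors passed over loci (adjusted p = 0.00636). For BAY 299-only regions every list had an adjusted p of 1, at gene ends and over loci alike. With 26 such genes and 103 such regions in all, these tests could detect little. With lists of equal length, AP-1 and immediate early genes passed over loci in the BAY 299-only direction (adjusted p = 0.00783). That cut removes the weakest DMSO peaks, so a BAY 299-only region there can have a DMSO call in the full lists.

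**Figure D3:**
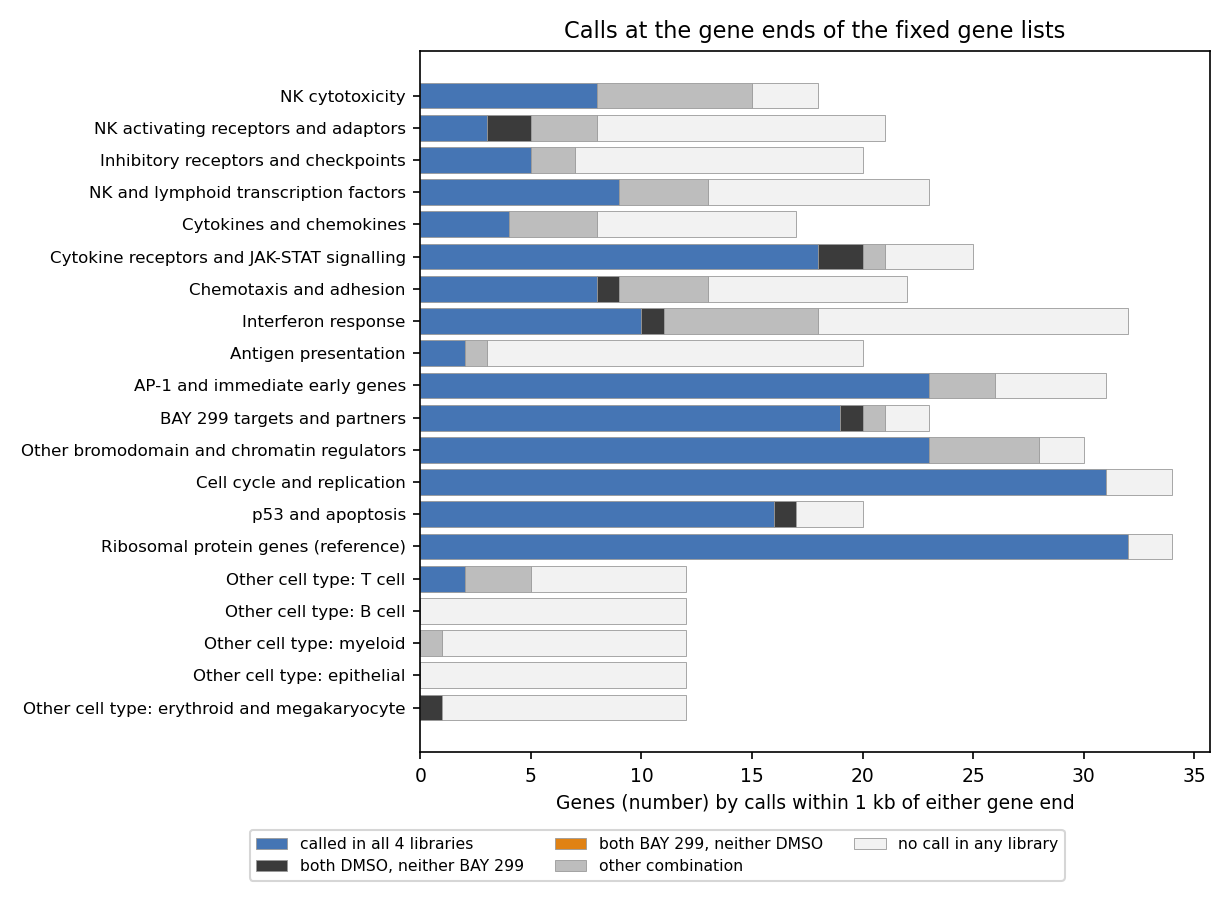
Each bar is 1 of the 20 gene lists, and its length is the number of genes, divided by the libraries with a call within 1 kb of either gene end. Cell cycle and ribosomal protein genes were called in all 4 libraries with few exceptions, DMSO-only genes were at most 2 per list, and no list held a BAY 299-only gene.

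Of the targets of the compound, TAF1 was called in every library and BRD1 in none at its gene ends. The gene-end region of TAF1 lay on chromosome X (71365856 to 71366586), and a further region inside the gene was DMSO-only (71492604 to 71493065). Inside BRD1, BAY 299 replicate 2 alone had a call, 1496 bp from the gene end (chromosome 22, 49826130 to 49826377). Of the 23 targets and partners, 19 were called in all 4 libraries, including KAT7 and MEAF6, partners of BRD1, its paralog BRPF1, and TBP and TAF7 of TFIID. TAF11 was DMSO-only (chromosome 6, 34887934 to 34888360, percentiles 32.1 and 32.9). CD274, which encodes the checkpoint ligand PD-L1, and IFNG were called at their gene ends in all 4 libraries (chromosome 9, 5450351 to 5450957, and chromosome 12, 68159413 to 68159943). A call in every library does not mean equal strength. The IFNG region ranked at percentiles 57.6 and 49.5 in DMSO replicates 1 and 2, and 45.3 and 19.2 in BAY 299 replicates 1 and 2. In the same order, the CD274 region ranked at 48.6, 39.7, 39.9 and 32.0. PDCD1, the gene of the receptor PD-1, had no call within 10 kb in any library.

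The strongest DMSO-only regions at gene ends lay in the middle of the DMSO lists. The first was at GPC5, a glypican gene (chromosome 13, 91398360 to 91398684, percentiles 53.8 and 68.3), followed by PLAAT2, ARL6IP5, SOAT2, ARMC7 and B3GNT7. The percentiles were 47.0 and 45.9 at PLAAT2, and 45.2 and 46.6 at ARL6IP5. CHCHD1, RYK, NBPF8, LRRC70, TIGD3 and LRRC34 completed the 12. Away from gene ends, the strongest were 2059 bp from DCAF13 (chromosome 8, 103445513 to 103445809), inside ATF3, a stress-response transcription factor gene (chromosome 1, 212567099 to 212567397, percentiles 83.9 and 63.2), and inside ARHGDIB and LRRFIP1. The fifth lay 1835643 bp from the nearest protein-coding gene end, that of WSB1. Without a filter for artefact-prone sequence, an artefact at this place cannot be told from a difference in accessibility.

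Each of the 12 strongest BAY 299-only gene-end regions had a percentile of 32.5 or lower in at least 1 BAY 299 list. They were led by DNAJB12, a co-chaperone gene (chromosome 10, 72332028 to 72332249, percentiles 32.5 and 34.6), TM7SF3 (29.3 and 57.8) and CFAP57 (38.8 and 29.2). TM6SF1, GEMIN6, DHX37, CDKAL1, NEMP2, KCMF1, L3MBTL3, WDR1 and SLCO3A1 followed. These last 3 lost the pattern at a −log10 q of at least 5, and WDR1 and SLCO3A1 also at equal list length. Away from gene ends, the strongest lay 189543 bp from SHCBP1 (chromosome 16, 46388606 to 46389047, percentiles 70.4 and 90.0), and the next lay near or inside MBOAT4, NEK1, GIPR and TNFRSF13B. The region far from SHCBP1 may also be an artefact, since no filter for such sequence was applied.

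Calls at markers of other cell types lay mainly at T cell genes. No library had one at any of 12 B cell or 12 epithelial markers, CD68 was called in 3 libraries among 12 myeloid markers, and among 12 T cell markers CD3E and CD8A were called in all 4, CD28 and CD3D in 3, and CD6 in 1. KLF1 was DMSO-only among 12 erythroid and megakaryocyte markers (adjusted p = 0.229), a pattern lost at equal list length.

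Of the regions shared by the 4 libraries, none passed limma's test after adjustment for the number of regions. Among the stronger 5185 regions called in all 4 libraries, limma called 0 at an adjusted p below 0.05 and 276 at an unadjusted p below 0.05, where chance gives 259. The other divisions of the libraries gave 244 and 220. Over all 10371 regions limma called 0, with 575 at an unadjusted p below 0.05 and 519 by chance, against 482 and 480 in the other divisions. The log2 difference was taken relative to the library medians. Its 95% interval lay within 1 on either side of 0, a 2-fold difference, for 98.7% of the stronger 5185 regions. Over all 10371 shared regions this held for 93.0%. Each interval covers 1 region at a time and measures only the spread between these libraries. Centring removes any change common to all regions, and regions not called in every library did not enter. In simulated data for this comparison over 5185 regions, 98% of 2-fold and 44% of 1.5-fold differences were recovered with 9 false calls, so differences of 1.5-fold or less could have been missed. The simulation gave every region the same spread and changed 50 regions at each fold. Real regions may differ in spread, so the real shares recovered may be lower, also for 2-fold differences.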

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

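Peak numbers were lower with BAY 299 under every alternative, with differences from -3957.5 without BAY 299 replicate 2 to -1293.5 without BAY 299 replicate 1. The gene-end odds ratios stayed below 1 and past their threshold in every alternative, including the one matched on strength that was added after the data were seen. Regions called only in a pair of libraries that mixes treatments also had low gene-end shares. These odds ratios therefore describe regions called in part of the libraries and do not bear on treatment. Counts of regions moved more. At a −log10 q of at least 5 there were 848 DMSO-only and 65 BAY 299-only regions, and the ratio rose to 13.05. At equal list length there were 388 DMSO-only and 305 BAY 299-only regions, a ratio of 1.27, and 1 list (AP-1 and immediate early genes) passed for BAY 299-only loci. At 50% reciprocal overlap there were 393 BAY 299-only regions and the ratio was 3.0, which counts peaks whose edges differ. Leaving out 1 library asks for 1 call in the group that lost it and still for 2 in the other. This gave 1360 to 3035 DMSO-only regions, 348 to 1319 BAY 299-only regions, and ratios from 1.03 to 8.72. Because the groups are held to unlike rules, these ratios do not show how the excess depends on each library. Leaving out 1 library also gave 0 to 3 lists lost at gene ends (3 without DMSO replicate 1) and 0 to 1 over loci (NK and lymphoid transcription factors, without DMSO replicate 2). Of the 48 named regions, 38 kept their pattern at the stricter threshold and 35 at equal length. Most losses fell on list members: at equal length CXCR3, TAF11 and MKI67 kept the pattern, and HCST with TYROBP, FLT3LG, STAT5B with STAT5A, CXCR4, GBP1, EZH2, KAT2A, E2F1, BID, KLF1 and KLRC1 did not, nor did WDR1 and SLCO3A1 among the strongest regions. At the stricter threshold GBP1, KAT2A, E2F1, BID, KLF1, KLRC1, MKI67, L3MBTL3, WDR1 and SLCO3A1 lost it. At equal length a region loses a call when its own peak ranks below the cut, so these losses restate the ranks. The cause of these shifts was not tested here beyond the construction of each alternative. With the replicate number as a block the difference in peaks was -2625.5 ± 1479 (SD of 2 differences, exact permutation p = 0.5, the smallest possible). The numbers share no label of a batch, the correlation of deviations across regions was 0.0067, and between treatments the overlap of libraries with the same number exceeded that with different numbers by 0.00780. The motif alternatives were not run. The effect of thinning was counted as union regions with a call, which are fewer than peaks. Thinning to equal background depth took the DMSO libraries from 15932 and 16497 to 15588.5 and 15724.5 such regions, against 12272 in BAY 299 replicate 1. Matching the pileup in shared regions as well took them to 14618 and 14763.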

Other observations

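Chosen after the result was seen were the tests that BAY 299 replicate 1 stands apart, that reads matching alternate haplotypes were left out and that the chromatin was closed, the test of the major histocompatibility complex against other genes, and the tests by chromosome. The comparison of gene-end shares at equal list length between DMSO-only and BAY 299-only regions was also made after the data were seen.

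The major histocompatibility complex, which holds most of the antigen presentation genes, was almost empty in all 4 libraries. From HLA-F to HLA-DPB1 (chromosome 6, 29723434 to 33089696) there was 1 region, and 2 of 128 protein-coding genes had a gene-end call, against 48.5% of other genes (Fisher's exact p = 1.76e-33). Flanks of the same length had calls at 52.1 and 43.8% of genes. The interval holds BRD2, TNF, LTA, LTB, TAP1, PSMB9 and the HLA genes, and 16 of the 20 antigen presentation genes lay in it or up to TAPBP. Of the 34 ribosomal protein genes the 2 without a call were RPS18, just above the interval (33272075 to 33276511), and RPS9 on chromosome 19 (54200858 to 54207647), a place chosen after its value was seen.

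For these missing calls, a candidate explanation is that reads also matching alternate haplotype sequences of the build were left out. The leukocyte receptor complex from LAIR1 to NCR1 (chromosome 19, 54351384 to 54938208), which also has many alternate haplotypes, had calls at 0 of 20 genes (Fisher's exact p = 2.4e-06 against other genes), and the lists held 33 peaks on alternate sequences, 11 of them of chromosome 6. Closed chromatin in these cells was not decided. Its test on ribosomal protein genes had 1 gene inside the interval extended to TAPBP, RPS18, and 32 of 33 called outside. With these totals its Fisher's exact p of 0.0588 was the smallest it could give. No biological explanation by treatment applies, because the gap was in both groups.

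More regions were DMSO-only than BAY 299-only. Lower depth alone was to bring the ratio to 1.5 or less after thinning to equal background. It stayed at 6.83 ± 0.269 (SD over 100 draws), so depth as measured here did not account for the excess. Thinning to equal pileup in shared regions as well left 4.03 ± 0.263. Read extension is not given, so the background may not measure depth alone. Neither thinning made the lists equally long, and the pileup match used only regions called in all 4 libraries. With lists cut to equal length the ratio was 1.27 (388 against 305), so lower depth or signal is not excluded as part of the cause. After the second thinning, regions missing in BAY 299 replicate 1 alone were 2.70 times those missing in the next library. This is a pattern that 1 library standing apart would give. A treatment effect common to both BAY 299 libraries cannot be told apart from this, as the treatment division then exceeded the larger of the others 1.18 times, below the bound of 1.5 set for it. That bound was too strict to exclude an effect, because BAY 299 replicate 2 also kept calls in fewer regions (13976) than the DMSO libraries (14618 and 14763) after thinning.

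At equal list length BAY 299-only regions lay at gene ends more often than DMSO-only regions (42.3 against 19.8%, odds ratio 2.96, Fisher's exact p = 1.55e-10). Low signal over background in BAY 299 replicate 1 is a candidate explanation, because the pair with that library had the higher share in both other divisions as well. The shares were 39.8 against 29.9% (odds ratio 1.55, Fisher's exact p = 0.016) and 39.5 against 25.1% (odds ratio 1.95, Fisher's exact p = 1.39e-04). An effect of BAY 299 on top of this was not tested.

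Among the 10 regions that ranked highest in all 4 lists, 5 overlapped pseudogenes of mitochondrial origin, such as MTND2P28 and MTATP6P1 on chromosome 1. Chromosome 20 held 4.59% of DMSO-only regions and 2.81% of those in all 4 libraries, and chromosome 1 held 6.99 and 10.0% (Fisher's exact test, adjusted p = 0.0468 for both over 23 chromosomes).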
